A study of Homo sapiens with 2 samples.

How the data were processed

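DNase-seq was performed on deproteinized genomic DNA from K562 and MCF7 cells, with 1 library for each line (2 samples in all). Per the labels' protocols, DNA was purified with a column kit and repeated phenol-chloroform extraction. It was digested with DNase I, and digests resembling those of a typical DNase-seq experiment were pooled within each line before library construction. Reads were processed with CASAVA 1.8 and BWA against hg19, per the submitters' processing notes, which give no role or order for these tools. The read filters and the rule that assigns a cut to a hexamer are not given in the sources used here.

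The authors deposited, for each line, 1 value per hexamer for all 4096 hexamers, taken here as a linear ratio: the values are positive, none is 0, and their mean is 1.13 in K562 and 1.11 in MCF7. The files have no header, and what the ratio is divided by is not given in the sources used here, so values are read as relative propensities within a line. The total number of cuts and the counts per hexamer are unknown. No counting interval or limit of detection can therefore be given, and the effect of depth on low values cannot be judged. A hexamer covered by few reads has a larger error, which these values do not show. The removal of unmappable positions and of amplification duplicates, if any, could shift hexamers that are frequent in repeats.

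All computations were made in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1; figures were drawn with Matplotlib 3.10.9. Values were put on the log2 scale without a pseudocount and centred on the median hexamer of each line. The line ratio is the difference of these centred values, K562 minus MCF7. Base effects came from a least-squares fit with effects summing to 0 at each position. Shares of variance of the fits of single bases, neighbours and all pairs were taken on hexamers left out of the fit, in 10 folds. A hexamer and its reverse complement were in the same fold. The shares of a single pair of positions and of G+C count were taken over all hexamers, with none left out. The CpG contrast at a pair of positions is the median of the 256 hexamers with CG there minus the median of the 256 with GC there. Lists of hexamers were placed by their median among 10000 random lists of equal size. The random lists were matched on G+C count for CpG within a line, and on mean propensity of both lines in 20 bins for line ratios. They were unmatched for the site lists within a line. With 1 library per line, no p-value was computed across hexamers, which are neither replicates nor independent of each other. The smallest difference the lines could show by chance is not known.

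The lists of sites (E-box, AP-1, CRE, GATA, ETS, nuclear and steroid receptor half-sites, TATA box, SP1, CTCF, NRF1, forkhead, SRF and p53, with both strands), A-tracts, runs of G, TATA and CGCG, as well as the contrasts and the rule for naming hexamers, were fixed before the data were examined. The rule names the 10 highest and 10 lowest hexamers by mean centred log2 propensity, the 5 with the largest ratio in each direction between the lines, and the highest and lowest member of a list. Several site lists hold only 2 to 5 hexamers. The alternatives were averaging of strands, omission of the lowest 5% of hexamers or of the extreme 1% at each end, the linear scale, other centring, quantile normalization, correction for G+C count, omission of CpG hexamers and other CpG controls. Weighting hexamers by their count in a genome was planned and not run, since no genome was used here. The statistics were tested on a simulated table of 4096 hexamers with the base effects of K562 and an SD of 0.1. Planted line differences of -0.3 (CG at positions 4 and 5) and 0.4 (CG at positions 5 and 6) were recovered as -0.32 and 0.37.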

Results

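The cleavage preference of DNase I was measured on purified human DNA from 2 established cell lines, K562 (chronic myelogenous leukaemia) and MCF7 (breast adenocarcinoma). DNase I is the endonuclease used to map open chromatin. On DNA stripped of protein, no bound factors or nucleosomes shape its cuts. The series concerns the use of this sequence bias in detecting transcription factor footprints. There was 1 library per line, so no value has a replicate error and no difference between the lines could be tested against replicates. Each library is summarised as 1 cleavage propensity for each of the 4096 hexamers, a positive ratio whose denominator is not given in the sources used here. The number of reads behind each value is unknown. Positions are counted from 1 at the 5′ end of the hexamer; the place of the cut within the hexamer is not given in the sources used here. No genomic coordinates apply, since each value is taken over the occurrences of a hexamer and not at a locus.

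Cleavage propensity varied widely with sequence, and the same hexamers stood at both ends in the 2 lines. The most readily cut hexamers were ACTGCC, ACTCCC and ACACCC, with propensities of 10.9, 11.1 and 11.2 in K562 and 10.7, 10.4 and 10.3 in MCF7. The least readily cut was CAATTA, at 0.0411 in K562 and 0.0480 in MCF7. The highest value exceeded the lowest 272-fold in K562 and 223-fold in MCF7. The 95th percentile of the hexamers exceeded the 5th 29.5-fold in K562 and 28.9-fold in MCF7. The median propensity was 0.700 in K562 and 0.690 in MCF7. The 409 highest hexamers held 36.3% of the summed propensity in K562 and 35.9% in MCF7.

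The 10 hexamers with the highest mean of both lines had a common layout. A stood at position 1 in 9 of them, C at position 2 in 9, A or T at position 3 in all 10, C or G at position 4 in all 10, and C at position 5 in 9. After the 3 above, they were ACAGCC, ATACCC, ACTCCT, ACAGGC, ACTGCA, ACTCCA and TCTGCC, with K562 values from 8.29 to 9.20 and MCF7 values from 8.04 to 8.96. The 10 lowest all had T at positions 4 and 5, and 8 of them had A at position 2. They were CAATTA, CAGTTA, CGATTA, CAATTT, CGATTT, GAGTTA, GAATTA, GATTTA, GAATTT and AAATTT, with values of at most 0.0537 in K562 and 0.0596 in MCF7. The 10 highest hexamers of K562 were also the 10 highest of MCF7, and 8 of the 10 lowest were shared, where independent lists would share 0.0244.

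The base at each position was then related to propensity, as log2 values centred on the median hexamer. Positions 2 and 5 had the widest effects. At position 2, C was highest and A lowest, with effects of 0.89 and -1.06 on the log2 scale in K562 and 0.87 and -1.06 in MCF7. At position 5, C was highest and T lowest, with effects of 0.93 and -1.22 in K562 and 0.83 and -1.23 in MCF7. The best and worst base thus differed 3.86-fold in K562 and 3.81-fold in MCF7 at position 2, and 4.44-fold and 4.17-fold at position 5. Position 3 had the narrowest range, 1.64-fold in K562 and 1.69-fold in MCF7, with T highest and G lowest. At position 1, A was highest (0.66 in K562, 0.67 in MCF7) and C lowest (-0.67 and -0.68). At position 4, C (0.55 and 0.52) and G (0.35 and 0.29) lay above A (-0.54 and -0.56) and T (-0.36 and -0.25). C was highest at position 6, at 0.65 in K562 and 0.62 in MCF7.

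**Figure D1:**
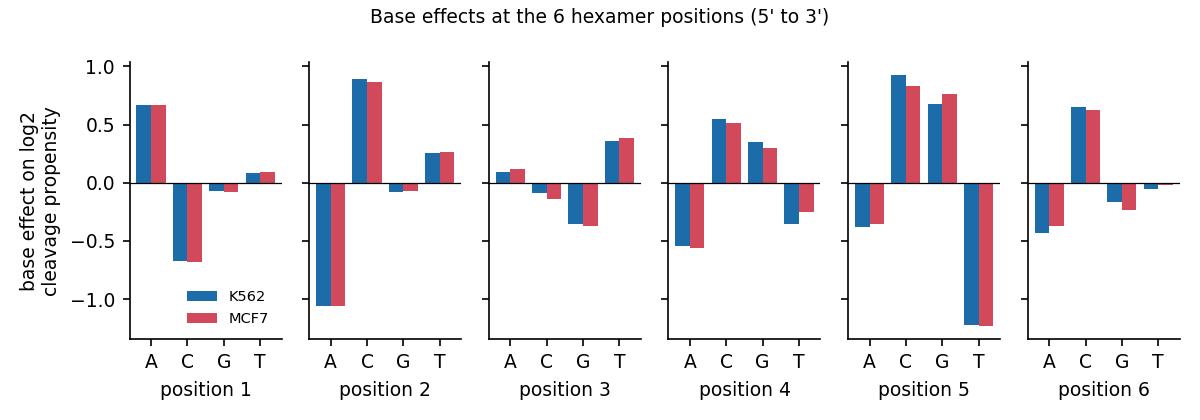
Effect of each base (A, C, G, T on the horizontal axes) at the 6 hexamer positions on log2 cleavage propensity, from a least-squares fit per line with effects summing to 0 at each position; blue bars are K562 and red bars MCF7, 1 library each, with no error bars. The widest spans are at position 5 (C against T) and position 2 (C against A), and the 2 lines have nearly equal bars.

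On the log2 scale single bases accounted for most of the variation between hexamers, and neighbouring bases for most of the rest. A fit of single bases (18 terms) explained 86.6% of the variance of held-out hexamers in K562 and 85.5% in MCF7. Adding pairs of neighbouring bases (63 terms) brought this to 96.4% and 96.2%, and all pairs of positions (153 terms) to 98.2% and 98.0%. The pair at positions 4 and 5 carried the largest neighbour contribution, 4.34% of the variance in K562 and 4.06% in MCF7 (over all hexamers, with none left out). At that pair, TA lay above the sum of its single-base effects by 0.54 in K562 and 0.62 in MCF7 (log2). TT lay at -0.60 and -0.54 relative to that sum, and AA at -0.43 and -0.41. At positions 1 and 2, TT (-0.44 and -0.45) and AA (-0.35 and -0.36) were likewise below their sums, whereas AT (0.25 and 0.26) and TA (0.23 and 0.25) were above them. At positions 5 and 6, TG was highest relative to its sum (0.46 and 0.52). On the linear scale, single bases explained 64.3% of the variance in K562 and 63.6% in MCF7. Neighbours there added 11.4 and 12.3 percentage points and the other pairs a further 15.1 and 14.0, so neighbours did not hold most of the rest. With strands averaged, on the log2 scale, the other pairs added 3.71 and 3.11 points beyond neighbours.

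Hexamers richer in G and C were cut more readily, with a wide spread at each composition. The median of the 64 hexamers made of A and T was -1.98 in K562 and -1.83 in MCF7 on the centred log2 scale. The median of the 64 made of G and C was 0.74 and 0.56. Averaged over positions, an additional G or C was accompanied by a 1.35-fold higher propensity in K562 and a 1.31-fold higher one in MCF7. This did not hold at each position, since C and G lay below A and T at positions 1 and 3 in both lines. In K562 the effects of C, G, A and T were -0.67, -0.07, 0.66 and 0.08 at position 1. At position 3 they were -0.09, -0.36, 0.09 and 0.36. G+C count alone accounted for 12.8% and 10.4% of the variance over all hexamers, with none left out.

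Cleavage depended on which strand was read. For the 2016 pairs of a hexamer and its reverse complement (64 palindromes left out), Pearson's r of log2 propensity across hexamers was 0.32 in K562 and 0.37 in MCF7, and Spearman's rho was 0.34 and 0.38. Hexamers are not independent replicates, and no p-value is attached to these correlations. The 2 members of a pair differed by a median of 2.25-fold in K562 and 2.16-fold in MCF7. More than 2-fold differences were present in 1125 pairs in K562 and 1094 in MCF7. The widest was ATTCCC against GGGAAT, at 6.81 and 0.144 in K562 and 6.48 and 0.144 in MCF7. On the linear scale r was 0.138 in K562 and 0.177 in MCF7.

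Hexamers of transcription factor sites and of structural elements, from lists fixed in advance, stood at different levels of the bias. Each list's median was compared with 10000 random lists of the same size, which describes these libraries and is not a test between conditions. Of 18 lists, 4 lay below the 2.5th percentile of random lists in both lines, 1 lay above the 97.5th in both, and 13 lay between these limits in both. The 80 hexamers with AAAA or TTTT (A-tracts, which have a narrow minor groove) had medians of -1.83 in K562 and -1.69 in MCF7, lower than every random list, and 8 of 80 lay above the median hexamer in K562 and 10 in MCF7. Within this list GATTTT was lowest (0.0622 and 0.0639) and TTTTGC highest (1.72 and 1.81). The 5 TATA box hexamers, a core promoter element, had medians of -1.99 and -1.97 (percentiles 0.92 and 0.97), with none above the median hexamer. TATAAA was lowest at 0.124 and 0.131. The 47 hexamers containing TATA had medians of -0.77 and -0.64 (percentiles 0.41 and 2.04). The 5 E-box hexamers, sites of basic helix-loop-helix factors, had medians of -1.81 and -1.90 (percentiles 1.57 and 1.24). All 5 were below the median hexamer, from CATATG (0.166 and 0.153) up to CACGTG (0.264 and 0.232). CATATG and CACGTG both have C at position 1, A at position 2 and T at position 5, the lowest base at each. Their low place is thus not separate from the single-base effects given above. The 80 hexamers with GGGG or CCCC had medians of 0.64 and 0.62 (percentiles 99.85 and 99.82), and 57 of 80 in K562 and 56 in MCF7 were above the median hexamer. The same 5 lists lay outside random lists in both lines with strands averaged, without the lowest 5% of hexamers and on the linear scale. Mean centring and quantile normalization keep the order of hexamers, and the correction for G+C count acts on the line ratio only. These alternatives therefore could not test the place of a list within a line. The random lists here were not matched on G+C count. All hexamers with 5 G or C had medians of 0.64 in K562 and 0.59 in MCF7, close to those with GGGG or CCCC. All hexamers with 1 G or C had medians of -1.07 and -0.98, below those with TATA and above the A-tracts. The places of hexamers with GGGG or CCCC and with TATA are thus not separate from G+C count. Relative to the mean of all hexamers in place of the median, every list's median was lower by the same amount (-0.69 in each line), which put the list with GGGG or CCCC at -0.06 in K562 and -0.07 in MCF7. Without the lowest 5% of hexamers the A-tract medians were -1.19 and -1.08.

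The other factor sites lay within the range of random lists, and several held both well and poorly cut hexamers. The medians in K562 and MCF7 were -1.10 and -1.18 for ETS, -0.87 and -0.86 for AP-1, -0.85 and -0.88 for p53 and -0.31 and -0.15 for GATA. They were 0.08 and 0.14 for forkhead, 0.15 and 0.40 for SRF, 0.55 and 0.47 for CTCF, and 0.88 and 0.79 for NRF1. They were 1.06 and 0.86 for SP1, 1.19 and 1.17 for CRE, 1.25 and 1.30 for nuclear receptors, and 1.28 and 1.38 for the glucocorticoid and androgen receptor half-site. Several of these medians depended on the processing. With strands averaged, NRF1 was at 1.81 and 1.94, above random lists in both lines (each value then stands for both strands), and SRF was at 0.66 and 0.89. CTCF was then at 0.12 and 0.23, forkhead at -0.27 and -0.10, ETS at -0.57 and -0.61, and p53 at -0.32 and -0.34. Without the lowest 5% of hexamers, ETS was at -0.50 and -0.46 and SRF at 0.50 and 0.79. With means on the linear scale in place of medians, forkhead was at -0.57 and -0.42, SRF at -0.44 and -0.22, CRE at 0.09 and 0.24, and p53 at -0.18 and -0.12 (log2 of the list mean over the mean of all hexamers). On that scale GATA was at -0.92 and -0.73, SP1 at 0.47 and 0.36, and the glucocorticoid and androgen receptor half-site at 0.60 and 0.70. The change of reference from the median hexamer to the mean shifts a log2 value by -0.69 in each line. In the NRF1 site, ATGCGC was at 4.35 in K562 and 4.75 in MCF7, and CGCATG at 0.202 and 0.214. In the site of the insulator protein CTCF, GCCCCC was at 3.73 and 3.35, and CACTAG at 0.166 and 0.173; 11 of its 18 hexamers lay above the median hexamer in each line. In the CRE, the site of CREB and ATF factors, TGACGT was at 1.60 and 2.16, and GACGTC at 0.268 and 0.238. Among ETS sites, CTTCCT was at 1.63 and 1.60, and CAGGAA at 0.0874 and 0.0936. In the nuclear receptor half-site TGACCC was at 3.60 and 3.38, and GGGTCA at 0.530 and 0.557. In the glucocorticoid and androgen receptor half-site, AGAACA was at 1.91 and 1.96, and TGTTCT at 1.52 and 1.64. In the GC box of SP1, CCGCCC was at 2.46 and 2.18, and GGGCGG at 0.575 and 0.687. In the half-site of p53, ACATGT was at 3.11 and 3.33, and GACATG at 0.211 and 0.182. In the SRF site ATATGG was at 1.77 and 1.97, and CATATA at 0.102 and 0.0985. Of the forkhead hexamers GTTTAC was at 1.37 and 1.56, and TGTTTA at 0.174 and 0.216. All 4 AP-1 hexamers, sites of FOS and JUN dimers, lay below the median hexamer, from GACTCA (0.242 and 0.245) to TGACTC (0.613 and 0.548). Of the 8 GATA hexamers 3 lay above it, with TGATAA lowest (0.408 and 0.461) and AGATAG highest (0.733 and 0.886). The 47 hexamers with CGCG had medians of 0.52 and 0.42 (percentiles 95.6 and 92.2), from CGCGAA (0.138 and 0.130) to ACGCGC (4.86 and 4.35).

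The profiles of the 2 lines were close. Across the 4096 hexamers Pearson's r of log2 propensity was 0.993 and Spearman's rho 0.992. The log2 ratio of K562 to MCF7, each centred on its median, had an SD of 0.18 and ran from -0.64 to 0.68. A difference of more than 1.25-fold was present for 363 hexamers and of more than 1.5-fold for 27. The 27 became 14 after correction for G+C count. With strands averaged, which leaves 2080 distinct values, 117 (5.63%, against 8.86% of the 4096 hexamers) were more than 1.25-fold apart and 1 more than 1.5-fold (0.048% against 0.659%). These differences were concentrated in hexamers with a CpG. Of the 363 hexamers, 330 had at least 1 CpG, and 293 had it at positions 4 and 5 or at positions 5 and 6. All 27 beyond 1.5-fold had a CpG. The SD of the log2 ratio was 0.27 over the 1185 hexamers with a CpG and 0.11 over the 2911 without one, where r was 0.997.

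**Figure D2:**
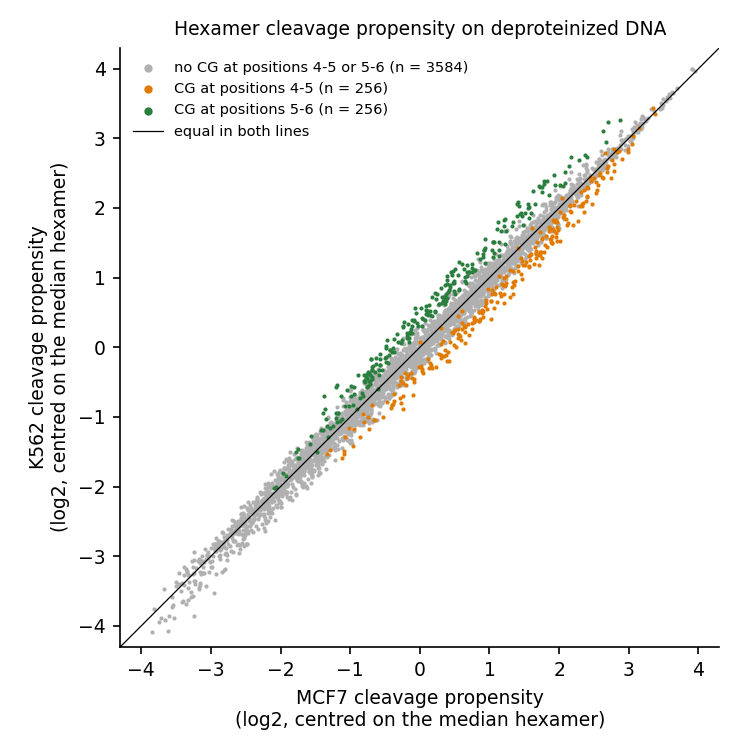
Cleavage propensity of the 4096 hexamers in MCF7 (horizontal axis) and K562 (vertical axis), log2 and centred on the median hexamer of each line; each point is a hexamer, orange with CG at positions 4 and 5, green with CG at positions 5 and 6, grey otherwise, and the black line marks equal values. The points follow the line of equality (r = 0.993), with most orange points below it and most green points above it.

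The 2 lines differed in opposite directions according to where the CpG lay, a comparison made because purified DNA keeps its cytosine methylation. With CG at positions 4 and 5, propensity was higher in MCF7 for 248 of 256 hexamers, with a median of 1.24-fold (log2 K562/MCF7 of -0.31, SD 0.15 across hexamers). With CG at positions 5 and 6, propensity was higher in K562 for 254 of 256 hexamers, with a median of 1.31-fold (log2 0.39, SD 0.14). With CG at positions 3 and 4, it was higher in K562 for 247 of 256 hexamers, with a median of 1.16-fold (log2 0.21, SD 0.12). The medians were 0.08 with CG at positions 2 and 3 and 0.01 at positions 1 and 2. The 5 hexamers furthest towards K562 were TGTCCG, GTTCCG, AGGCCG, CGAACG and TGCCCG, all ending in CG, at 1.58-fold to 1.60-fold. TGTCCG was at 2.98 in K562 and 1.83 in MCF7. The 5 furthest towards MCF7 were GACCGT, CGGTTA, TACCGT, CTCCGT and CAACGT, at 1.51-fold to 1.56-fold. GACCGT was at 0.380 in K562 and 0.583 in MCF7, and all of these except CGGTTA had CG at positions 4 and 5.

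The log2 ratio was also set against hexamers with GC in place of CG at the same positions, which hold the same bases. Some of these hold a CpG beside the GC. Of the 256 with GC at positions 4 and 5, 64 have CG at positions 5 and 6 (median 0.39). Of the 256 with GC at positions 5 and 6, 64 have CG at positions 4 and 5 (median -0.18). The median with CG minus the median with GC was -0.35 at positions 4 and 5 and 0.40 at positions 5 and 6. It was 0.11 at positions 3 and 4, 0.04 at positions 2 and 3 and 0.00 at positions 1 and 2. With 1 CpG in the CG hexamers and none in the GC hexamers, it was -0.31 at positions 4 and 5 and 0.39 at positions 5 and 6. Against 10000 random lists matched on mean propensity, the median of the CG hexamers at positions 4 and 5 was below all, and those at positions 2 and 3, 3 and 4, and 5 and 6 were above all. The percentile at positions 1 and 2 was 99.6. Averaging each hexamer with its reverse complement brought the contrasts to -0.20 at positions 4 and 5 and 0.28 at positions 5 and 6, and by construction to the same values at positions 2 and 3 and at positions 1 and 2. The contrast at positions 3 and 4 was 0.19 on the linear scale and 0.07 against hexamers with those 2 bases swapped (a control chosen after the data were seen), and at positions 2 and 3 it was 0.10 and 0.09. Against the swapped control it was -0.27 at positions 4 and 5 and 0.33 at positions 5 and 6.

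**Figure D3:**
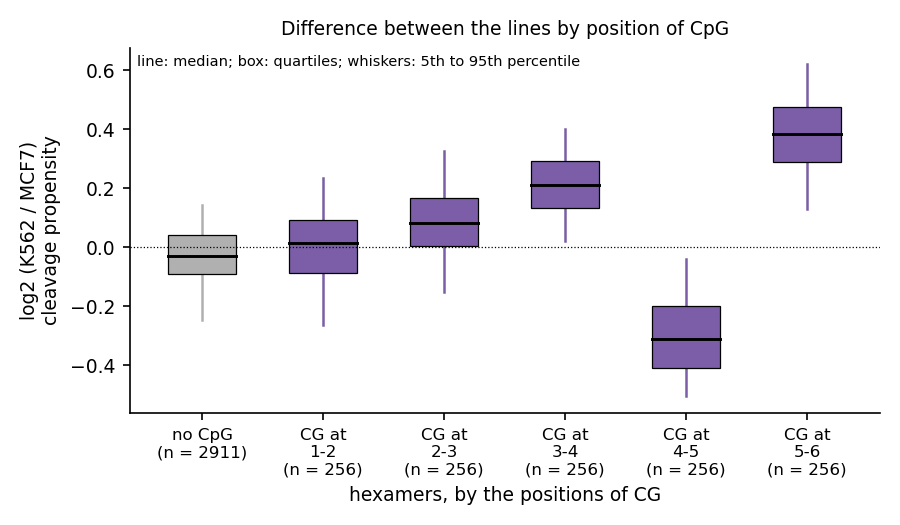
Log2 ratio of K562 to MCF7 cleavage propensity (vertical axis, 0 means equal in the 2 lines) for hexamers with no CpG and for hexamers with CG at each pair of neighbouring positions (horizontal axis); black lines are medians, boxes quartiles and whiskers the 5th to 95th percentiles across hexamers. The median is -0.31 with CG at positions 4 and 5 and 0.39 with CG at positions 5 and 6, against -0.03 with no CpG.

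Within each line, hexamers beginning with CG were cut less than those beginning with GC, and most of that difference followed from the single bases. With CG at positions 1 and 2 the median was lower than with GC there, by a log2 difference of -1.91 in K562 and -1.79 in MCF7, and it lay below every random list of equal G+C content. The single-base effects alone add up to a difference of -1.57 in K562 and -1.54 in MCF7. CG at positions 1 and 2 lay at -0.31 relative to the sum of its single-base effects in both lines, less far below than AA or TT. At positions 5 and 6 the difference was -0.87 in K562 and -1.29 in MCF7. At positions 2 and 3 it was 0.62 and 0.54, and at positions 3 and 4 it was -0.17 and -0.37. At positions 4 and 5 the difference was -0.31 in K562 and 0.14 in MCF7. At every pair of positions, CG lay below the sum of its single-base effects in both lines, from -0.34 to -0.14 in K562 and from -0.42 to -0.10 in MCF7. At positions 4 and 5 the single-base effects alone add up to a difference between CG and GC of -0.05 in K562 and 0.16 in MCF7. At each pair of positions other than 1 and 2, the direction of the difference between CG and GC in at least 1 line depended on the control. Against hexamers without CpG of equal G+C count, the difference in K562 and MCF7 was -0.23 and -0.29 at positions 2 and 3, -0.56 and -0.89 at positions 3 and 4, 0.50 and 0.83 at positions 4 and 5, and 0.014 and -0.39 at positions 5 and 6. With 1 CpG only it was 0.38 and 0.16 at positions 3 and 4 and -0.63 and -0.31 at positions 4 and 5.

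Between the lines, 6 of the 18 lists had a median log2 ratio outside the central range of random lists matched on mean propensity. The GATA hexamers were higher in MCF7 in 8 of 8 (median -0.16, percentile 0.47), and the E-box hexamers were higher in K562 in 5 of 5 (median 0.16, percentile 98.0). GATA hexamers such as AGATAG and TGATAA have T at position 4. Hexamers without CpG that have T there were higher in MCF7 in 811 of 840 (median -0.13). The GATA result cannot be told apart from that wider trend, which neither the matching nor the correction for G+C count removes. The E-box median is the ratio of CACGTG, which has CG at positions 3 and 4. Of all hexamers with CG there, 247 of 256 were higher in K562 (median 0.21). The E-box median is thus not separate from that CpG difference, and the source in the other E-box hexamers was not tested. A-tracts (median -0.08) and hexamers with TATA (-0.07) were higher in MCF7. Hexamers with GGGG or CCCC (0.07) and with CGCG (0.10) were higher in K562. The ratio moved with composition, from a median of -0.12 in hexamers without G or C to 0.14 in those made of G and C. After subtraction of the median at each G+C count, 2 of the 18 lists lay outside, GATA (median -0.09, percentile 2.23) and NRF1 (-0.11, percentile 2.27), of which only GATA was among the 6. The medians of the other 5 were then 0.14 for E-box hexamers (percentile 93.8), -0.002 for A-tracts, 0.01 for hexamers with TATA, -0.02 for those with GGGG or CCCC and 0.01 for those with CGCG. The 6 lists lay outside under every other alternative run on the line ratio. Of these, mean centring shifts every ratio alike and could not change the calls. SRF (median -0.17, percentile 3.14) joined them with strands averaged (-0.23), without the lowest 5% of hexamers (-0.22) and with quantile normalization (-0.17). With strands averaged the medians were -0.13 for A-tracts and 0.22 for CGCG.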

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

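The tests of G+C content and of genome composition, and the control with swapped bases, were chosen after the result was seen. The contrast of CG against GC at positions 4 and 5 had opposite signs in the 2 lines, -0.31 in K562 and 0.14 in MCF7 (log2). With 1 library per line the difference was not tested. The sign was not stable in either line. In MCF7 it was -0.04 when each hexamer was compared with the one having those 2 bases swapped, -0.07 on the linear scale, and -0.31 when only hexamers with 1 CpG were used. In K562 it was 0.50, and in MCF7 0.83, against CpG-free hexamers of equal G+C count. The gap between the lines was -0.27 with swapped bases, -0.32 on the linear scale and -0.31 with 1 CpG only.

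The difference between the lines at positions 4 and 5, and its opposite at positions 5 and 6, was weighed against technical explanations. G+C content does not separate CG from GC, yet the line ratio differed between them. The contrast was -0.35 (95% interval over resampled hexamers, -0.39 to -0.31) at positions 4 and 5 and 0.40 (0.36 to 0.42) at positions 5 and 6. These are the contrasts already given above and not a further test. Since both groups hold the same bases at those positions, these contrasts argue against a G+C trend as the source. The intervals here and below resample hexamers as if independent, which they are not. Such intervals describe the spread over sequences in these libraries and give no replicate error of a line difference. Genome composition, such as copy number or the background count of a hexamer over both strands, is equal for a hexamer and its reverse complement. The ratio differed between them by a median of -0.38 (-0.42 to -0.35) for CG at positions 4 and 5 and by 0.39 (0.37 to 0.42) for CG at positions 5 and 6, which argues against it. A candidate explanation is a difference in cytosine methylation between the lines, which was not measured here; if CpG-rich sequence is less methylated, the gap should be smaller with 2 or more CpGs. The gap was smaller at positions 5 and 6 (a change in size of -0.17, interval -0.24 to -0.09). It was not smaller at positions 4 and 5 (0.05, interval -0.06 to 0.11). The gap was taken over pairs of hexamers with those 2 bases swapped. With 2 or more CpGs there were only 39 such pairs at positions 5 and 6 and 21 at positions 4 and 5. Methylation thus stays open, as does a difference between the 2 libraries in preparation, which the design cannot separate from the line.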

How the results depend on the processing

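No paired analysis was possible because there is 1 library per line, and for the same reason no replicate was left out. Of 508 values recomputed under 11 alternatives, 35 changed sign. In 10 of these the value had been beyond 0.18 within a line or 0.11 between lines, or its list outside random lists. Of the rest, 136 moved and 362 moved little. Part of the 362 could not move, so their number does not measure stability. Mean centring leaves correlations and CpG line differences unchanged. The correction for G+C count leaves correlations and list medians within a line unchanged, and changes that keep the order of hexamers leave rho unchanged. With no replicates, a log2 value counted as moved when it shifted by more than those 2 sizes (the SD of the line ratio over all hexamers and over those without CpG). The line ratios of lists were an exception and were held to 0.18, not to 0.11. The SP1 ratio, 0.15 before and 0.005 after correction for G+C count, thus counted as moved little. Other values counted as moved beyond 1.5 times, taken on the unexplained part for correlations and shares of variance. The line differences at positions 4 and 5 and at positions 5 and 6 kept their direction under every alternative run, from -0.35 to -0.20 and from 0.28 to 0.45. Mean centring could not change them. The comparison with swapped bases was added after the data were seen; the cause of the shifts below was not tested unless the construction gives it. Depth is unknown, so its effect on the lowest hexamers is open.

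Averaging strands makes positions symmetric. The log2 of the 95th over the 5th percentile became 4.02 in K562 and 4.07 in MCF7, and the K562 range at position 5 became 1.92. All pairs of positions then gained 3.71 and 3.11 further points over neighbours, and 117 and 1 of the 2080 distinct strand-averaged values (5.63% and 0.048%, against 8.86% and 0.659% of 4096 hexamers) differed between the lines by more than 1.25-fold and 1.5-fold. CG minus GC became -1.37 in K562 and -1.59 in MCF7 at positions 1 and 2 and at 5 and 6, with a line difference of 0.28. At positions 2 and 3 and at 4 and 5 it became -0.087 and 0.25, with a line difference of -0.20. The number of lists above random lists in both lines became 2.

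Without the lowest 5% of hexamers, the percentile range was 4.42 in K562 and 4.39 in MCF7, and CG minus GC at positions 1 and 2 was -1.69 in K562. On the linear scale, single bases explained 64.3% and 63.6%, neighbours gained 11.4 and 12.3 points and all pairs a further 15.1 and 14.0, reverse complements correlated at 0.138 and 0.177, and CG minus GC at positions 4 and 5 was -0.074 in MCF7. Without CpG hexamers, r was 0.9972 and rho 0.9972, the SD of the ratio was 0.11, 33 hexamers passed 1.25-fold and 0 passed 1.5-fold, and the MCF7 range at position 5 was 2.29. After correction for G+C count, 14 hexamers passed 1.5-fold and 2 lists had a ratio outside random lists, 1 of them (GATA) among the 6 before; the ratio became -0.024 for G-runs and 0.014 for TATA. Centring on the mean put G-runs at -0.058 in K562 and -0.067 in MCF7. Of the 35 changes of sign 22 were in medians of lists: besides those given here and in the account of the lists, they were the medians of CTCF, CGCG, forkhead and SRF under mean centring, and the line ratios of CRE (0.15 to -0.20), AP-1 and ETS with strands averaged and of the TATA box (-0.09 to 0.03) after G+C correction. Of 306 list values 84 moved. Mean centring gave 34 of these, and they had to move, since it shifts every list median within a line by -0.69. The linear scale, which also takes the mean as reference, gave 26. The number that moved therefore does not measure instability.

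The CpG contrast within a line depended most on its control. Against CpG-free hexamers of equal G+C count it was -1.72 in K562 at positions 1 and 2. In K562 and MCF7 it was -0.23 and -0.29 at positions 2 and 3, -0.56 and -0.89 at positions 3 and 4, 0.50 and 0.83 at positions 4 and 5, and 0.014 and -0.39 at positions 5 and 6. With 1 CpG only it was -2.07 in MCF7 at positions 1 and 2. In K562 and MCF7 it was then 0.23 and 0.21 at positions 2 and 3, 0.38 and 0.16 at positions 3 and 4, and -0.63 and -0.31 at positions 4 and 5. Against swapped bases it was 0.38 and 0.27 at positions 2 and 3, -0.66 and -0.95 at positions 5 and 6, and -0.041 in MCF7 at positions 4 and 5.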

Other observations

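The groups of hexamers by base and the test of G+C effects by position were chosen after the line ratios were seen. The bases beside a CpG went with the size of the line difference. With CG at positions 5 and 6, K562 was higher by 1.45-fold at the median when C preceded it, in 64 of 64 hexamers, and by 1.24-fold when T preceded it, in 63 of 64. The values were 1.31-fold after G and 1.26-fold after A. The base before this CG is at position 4. On the log2 scale the medians were 0.53 after C and 0.31 after T. In hexamers without CpG they were 0.10 with C and -0.13 with T at position 4, a gap about as wide. The gap between C and T is thus not particular to hexamers with a CpG. With CG at positions 4 and 5, MCF7 was higher by 1.29-fold when T followed and by 1.28-fold when A followed, in 64 of 64 hexamers each. It was higher by 1.13-fold, in 56 of 64, when C followed.

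Outside CpG the lines also differed by sequence. The median line ratios of the 4 bases spanned 0.23 (log2) at position 4, against 0.07 at position 6, 0.06 at position 5, 0.04 at position 2 and 0.03 at positions 1 and 3. Among hexamers without CpG, those with T at position 4 were higher in MCF7 in 811 of 840 (median log2 K562/MCF7 of -0.13), and those with C there were higher in K562 in 596 of 616 (median 0.10). The medians were -0.02 with A and -0.03 with G. TTA at positions 4 to 6 had a median of -0.32, with MCF7 higher in 56 of 56 hexamers, and this group was poorly cut in both lines (medians of -2.65 in K562 and -2.31 in MCF7). TA at positions 4 and 5 had a median of -0.23, with MCF7 higher in 224 of 224. CA at positions 4 and 5 had a median of 0.12, with K562 higher in 223 of 224.

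The ratio of K562 to MCF7 rose with G+C count by 0.046 (log2) per base. CpG content as the whole source is argued against, because the slope over hexamers without CpG was 0.81 times that over all (interval 0.74 to 0.89). Amplification by G+C content is a common technical source, and it should act on a fragment whichever hexamer position holds the G or C. In hexamers without CpG the effect of G or C was 0.12 at position 4. It was 0.02 at position 1, -0.003 at position 2, 0.04 at position 3, 0.009 at position 5 and 0.04 at position 6. An equal G+C effect at every position is thus argued against, though a small effect at positions other than 4 is not. The correlation of the ratio with that of the reverse complement was 0.14, but this decides nothing: G+C count alone accounted for a share of 0.14 of the variance and would give about that correlation, so the bound of 0.2 set beforehand could not tell. A difference in library preparation or digestion that acts on the base at position 4 may remain as a source, and no biological explanation was tested for it.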
